A study of Caenorhabditis elegans with 2 samples.

How the data were processed

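ChIP-seq of XND-1 with a C-terminal GFP-FLAG tag was done on whole young adult hermaphrodites, 2 biological replicates of 1 group, with an anti-GFP antibody and sonicated chromatin, per the labels. No paper, label or file header names the aligner, peak caller or IDR cut-off, which are therefore not given in the sources used here. Peaks were called per replicate and on both replicates pooled, with a control alignment, per the deposited descriptions of the files; these lists are loose and hold background regions meant as input for IDR. An IDR-thresholded list made from them was deposited beside them, and each list exists on ce10 and on ce11. The control alignment was not used here. The replicates are labelled as separate biological samples.

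Each list has 1 row per peak summit. The deposited signalValue is a score given to each peak by the authors' caller, with no unit named, and was used only to rank, filter or describe peaks within a list. The deposited q value of each peak, stored as −log10 q, was the same for all IDR-thresholded peaks on ce11 (3.78), so it could not rank them. Every one of the 1841 IDR-thresholded peaks was a row of the pooled list and among its 1841 highest scores. Peaks had a standard width of 460 bp in 50.1% of the IDR-thresholded list, and 1800 distinct intervals carried the 1841 summits. No total read count is given by any list, so depth per replicate is unknown and intervals on shares cover only the number of peaks or genes.

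All main results came from the ce11 lists, with the WBcel235 genome and gene annotation release 115, whose chromosome lengths hold every peak; the ce10 lists were used for counts per chromosome and overlaps between ce10 lists, and no coordinate was converted. The annotation gave 19973 protein-coding genes on the 6 nuclear chromosomes, and no peak lay on the mitochondrial genome. A gene was called bound when a summit lay 500 bp upstream to 200 bp downstream of an annotated 5′ end of one of its protein-coding transcripts. Features took precedence in the order promoter, coding exon, 5′ UTR, 3′ UTR, other exon, intron, intergenic. The 20 gene lists, the tests and the named-gene rule were fixed before the data were examined. Lists were made of gene names and name prefixes; 7 names found no protein-coding gene and were left out, and where several genes share a name, as among histones, each was counted. The lists overlap in a few genes.

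The share of peaks on X was compared with the share of chromosome length by an exact binomial test, and that of summits in promoters and near non-coding genes with 100000 circular shifts within chromosomes. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests at a threshold of 0.05 after Benjamini-Hochberg adjustment over the lists. Words of 6 bases were counted once per peak within 50 bp of the summit, a window of 101 bp, and each summit window was paired with 1 of its 2 flanks 300 bp away, the side drawn at random, for an exact McNemar test; the flank percentages are means over both sides. Replicate agreement was the share of IDR-thresholded peaks overlapped by at least 1 bp by as many top peaks of a replicate. Genes and peaks are not independent replicates, so p-values describe these lists and not a population of animals.

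The named genes are those nearest the 25 highest peaks within 500 bp, up to 4 bound members with the highest score per list, xnd-1 and unc-119, the genes at the 3 highest X peaks, and him-17, him-5, him-8, spo-11 and syp-1 to syp-4. Alternatives were each replicate's own top peaks in place of the IDR-thresholded list, its 921 strongest peaks, a list with 2 times as many pooled peaks, narrower and wider promoter windows, any overlap, other backgrounds, other word windows and the ce10 lists; others were added after the data were examined.

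Tests were tried on simulated data. Among 20 planted lists of 50 genes, the list test called 100% at 20% of members bound and 0% at 7% bound, and it called 0% of 100 random lists. The shift test called 3% of 100 simulations with no peak moved and 100% with 10% of the peaks moved to promoters. The word test called a word planted in 5% of windows and did not call it unplanted, when 1 other word was called. These windows were drawn at random places. The simulation therefore does not cover the difference in GC content between real summits and flanks, and gives no rate of false calls for them. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.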

Results

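The binding of XND-1 to the genome of Caenorhabditis elegans was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq). XND-1 is a chromatin protein of the worm germline, known for its enrichment on autosomes and for its role in crossover formation on the X chromosome. The worms carried XND-1 with a C-terminal GFP-FLAG tag, and chromatin was precipitated with an antibody against GFP from whole hermaphrodites collected as young adults, 50 h after release from starved L1 arrest. The series held 1 group with 2 biological replicates and no other condition, so the comparisons were made between chromosomes, genomic features, gene groups and replicates. All coordinates are on ce11 (WBcel235), 1-based. The list of peaks that passed the authors' irreproducible discovery rate (IDR) procedure held 1841 peaks, the pooled list before that step 24467, and the lists of replicates 1 and 2 held 22772 and 22364. The peak score, signalValue, ranged from 65.6 to 2548 over the IDR-thresholded peaks, with a median of 128. Read depth per replicate was unknown, because peak lists carry no read counts.

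The replicates placed most of their strongest peaks at the same loci. Among the 1841 top peaks of each replicate, those of replicate 1 overlapped 90.2% of the IDR-thresholded peaks by at least 1 bp (exact Clopper-Pearson 95% interval 88.8% to 91.5%), and those of replicate 2 overlapped 91.2% (89.8% to 92.4%). Random circular shifts of the peaks gave a mean overlap of 1.79% and 1.76%. Top peaks of both replicates overlapped 1514 IDR-thresholded peaks, and across those peaks, which are not independent replicates, Spearman's rho of the replicates' scores was 0.916. The IDR-thresholded list was made from the same libraries, so these shares are not an independent test of it.

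The X chromosome was nearly devoid of strong XND-1 peaks. Only 10 of the 1841 IDR-thresholded peaks lay on X, a share of 0.543% (exact 95% interval 0.261% to 0.997%), whereas X makes up 17.7% of the length of the 6 nuclear chromosomes (exact two-sided binomial p = 1.58e-136). Autosomes carried 22.2 peaks per Mb and X carried 0.564, a density 39.3 times higher on autosomes (exact 95% interval 21.3 to 82.1). Autosomes differed among themselves. Chromosomes I, II and III held 27.6, 27.5 and 27.4 peaks per Mb, chromosome IV held 17.8 and chromosome V held 14.6. The X share was 0.217% among the 921 strongest peaks, 1.47% in a looser list of 2 times as many pooled peaks and 0.822% in the IDR-thresholded list on ce10. Each replicate alone gave similar numbers, with 10 X peaks among the top 1841 of replicate 1 and 11 among those of replicate 2. X holds 13.7% of the protein-coding genes, yet 10 of its 2731 protein-coding genes were bound (0.366%), against 1324 of 17242 on autosomes (7.68%). Peaks are not independent of one another, so these p-values describe this list.

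**Figure D1:**
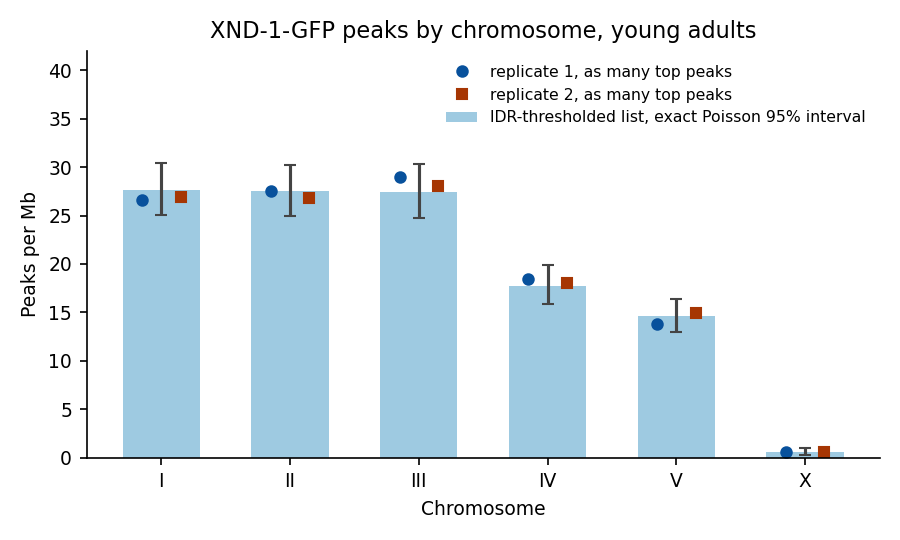
Peaks per Mb (y axis) on each chromosome (x axis), with bars for the IDR-thresholded list and their exact Poisson 95% intervals, and points for the top 1841 peaks of each replicate. X stands at 0.564 peaks per Mb and the lowest autosome, V, at 14.6.

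The strongest X peak ranked 374th of 1841 with a score of 301. Its summit lay at X position 182442, in the promoter of chkr-1 and 249 bp upstream of an annotated 5′ end. The next X peaks had scores of 130, at 12283107 in the promoter of C04B4.2, and 106, at 7232655. The latter summit lay inside F46H5.3, 84 bp upstream of an annotated 5′ end that is itself within the gene. The median score of X peaks was 80.4 and that of autosomal peaks 128. Down the pooled list the share of X rose, from 0.687% (exact 95% interval 0.376% to 1.15%) among ranks 1 to 2039 to 2.5% (1.87% to 3.28%) among ranks 2040 to 4078 and to 10.4% (9.06% to 11.8%) in the last of 12 rank bins. These bins were chosen after the data were examined.

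**Figure D2:**
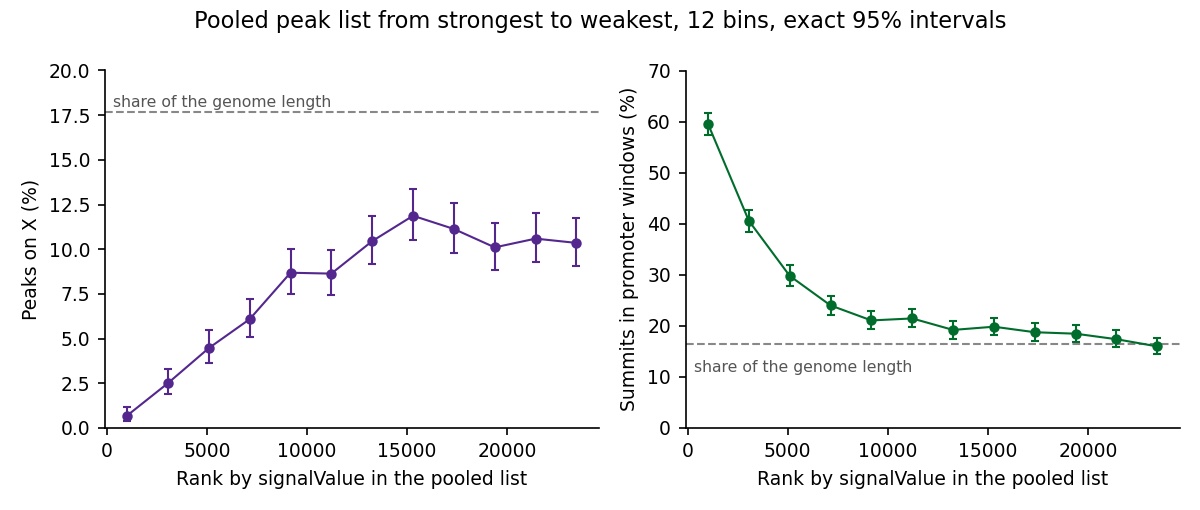
Percent of peaks on X (left y axis) and percent of summits in promoter windows (right y axis) against rank by signalValue in the pooled list (x axes), in 12 bins with exact 95% intervals, with dashed lines at the share of the genome's length. From the first to the last bin the X share went from 0.687% to 10.4% and the promoter share from 59.5% to 15.9%.

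XND-1 peaks were enriched at promoters, just upstream of genes. Promoter windows, taken as 500 bp upstream to 200 bp downstream of the annotated 5′ ends of protein-coding transcripts, held 1122 of the 1841 summits, or 60.9%. They cover 16.4% of the genome, and 100000 circular shifts of the summits within chromosomes placed 16.8% there on average and at most 27.3% (one-sided permutation p = 1e-05, the smallest the shifts can give). With the window narrowed to 200 bp upstream and 100 bp downstream, 32.3% of summits lay in it (permutation p = 1e-05). Promoter summits lay at a median of 174 bp upstream of the nearest 5′ end. Of the 1122, 278 lay in the windows of genes on both strands, so that 1 peak was counted for more than 1 gene. Coding exons held 47 summits (2.55%) where shifts gave 21.7%, and introns held 185 (10%) where shifts gave 30.4%. Intergenic sequence outside promoters held 399 summits (21.7%) and shifts gave 25.2%. Many annotated 5′ ends in worms are trans-splice sites rather than transcription start sites, so a distance to a 5′ end is not always a distance to a start of transcription.

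The strongest peaks included loci of genes that act in oogenesis, chromosome segregation and maternal RNA control; no enrichment was tested on this set. Of the 25 peaks with the highest scores, 19 had a protein-coding 5′ end within 500 bp and 6 did not. Ranks 1 and 2 were among the 6, at I:13310824 (2548, intergenic) and I:11580345 (2085, in an intron). Ranks 4, 7 and 8 were intergenic, at III:9617139 (2040), III:5663702 (1888) and II:14245080 (1879). Rank 20 lay in an intron, at III:10877743 (1416). The highest of the 19 was at cpg-1, which encodes a chondroitin proteoglycan of the eggshell, with its summit at III:4489126 and a score of 2040, against 920 and 1123 in the lists of replicates 1 and 2. Genes for chromosome segregation among the 19 were klp-18 (1916), a kinesin of the oocyte meiotic spindle, coh-3 (1369), a meiotic cohesin kleisin, sgo-1 (1424), which encodes a shugoshin, and hcp-1 (1317), a centromere protein. Regulators of maternal RNA were mex-1 (1737) and puf-11 (1495), and pid-5 (1549) acts in the piRNA pathway. Others were gpi-1 (1801), encoding glucose-6-phosphate isomerase, taf-12 (1794), a subunit of the general transcription factor TFIID, nasp-2 (1418), a histone chaperone, unc-101 (1344), an adaptor protein subunit, and kin-35 (1355). Genes known by their sequence names, F26F2.7 (2018), T19H12.2 (1708), F43G6.16 (1594), C01G8.1 (1550), E02C12.12 (1483) and H05C05.1 (1391), completed the set. The summit of the pid-5 peak, at V:4175799, lay 83 bp upstream of pid-5 and 159 bp upstream of coh-4, another cohesin kleisin gene on the opposite strand.

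Along autosomes, summits were moderately more frequent in the chromosome centres than length predicts. The centres, the middle 33.3% of each autosome's length, held 701 of 1831 autosomal summits, or 38.3% (exact 95% interval 36.1% to 40.6%; exact two-sided binomial p = 8.96e-06). The centres hold 38.1% of autosomal protein-coding genes, a share inside that interval. The difference between peaks and genes was not tested.

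Genes of the germline were bound far more often than other genes. Of 19973 protein-coding genes, 1334 (6.68%) had a summit in a promoter window, and 16 of the 20 gene lists differed from all other genes, 12 with more members bound and 4 with fewer (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over the lists). In the synaptonemal complex and meiotic axis list 10 of 15 members were bound (66.7%, exact 95% interval 38.4% to 88.2%, adjusted exact p = 1.08e-08), including coh-4 (score 1549), coh-3 (1369), syp-5 (820) and the cohesin gene rec-8 (664). Translational control of germline stem cells and oocytes had 25 of 39 bound (64.1%, 47.2% to 78.8%, adjusted exact p = 2.04e-19), led by the RNA-binding protein genes mex-1, puf-11, puf-3 (1163) and spn-4 (828). P granule and small RNA genes had 19 of 40 bound (47.5%, 31.5% to 63.9%, adjusted exact p = 4.67e-12). Among them were tofu-6 (734), the helicase gene glh-2 (717), the nuclear Argonaute gene hrde-1 (585) and znfx-1 (537). Genes of meiotic breaks, recombination and pairing had 16 of 43 bound (37.2%, 23% to 53.3%, adjusted exact p = 1.7e-08), with cosa-1 (1146), which marks crossover sites, dsb-2 (894), chk-2 (531) and zhp-3 (487) in front. Germline chromatin regulators had 11 of 35 bound (31.4%, 16.9% to 49.3%, adjusted exact p = 2.12e-05), led by lin-9 (959), lin-53 (459), lin-54 (264) and lin-61 (163). The strongest member, lin-9, and lin-54 and lin-53 encode subunits of the DREAM repressor complex. With the narrower promoter window these 5 lists kept their calls, but their excess over other genes fell from 60 to 36.7 percentage points for the synaptonemal complex, from 57.5 to 19.8 for translational control, from 40.9 to 21.7 for P granules, from 30.6 to 17.7 for recombination and from 24.8 to 11 for chromatin regulators. Among the 921 strongest peaks the excess was 21.3 points for P granules and 16.3 for chromatin regulators. The narrower window left 658 bound genes and the 921 strongest peaks 739, against 1334 in the main setting. The share among other genes fell as well, so fewer points alone do not mean a weaker contrast.

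Sperm protein genes were the exception among the germline lists, with 3 of 69 bound (4.35%, exact 95% interval 0.906% to 12.2%) against 6.69% of other genes (adjusted exact p = 0.628), a difference of −2.34 percentage points that ran from −6.27 to −0.804 over the alternatives and was never called. The bound members were spe-39 (828), spe-15 (205) and spe-5 (74.6). All 3 were among the 27 names given one by one, of which 1 found no gene. Most of the 69 members entered by the name prefixes msp and ssp, and none of those was bound. Whether peaks can be called equally well in such gene families was not tested. The spe-39 summit, at V:6785070, is the one that lay 167 bp upstream of spn-4, and spe-5 was not bound in the top peaks of replicate 2. Taken over the 6 germline lists, 84 of 241 members were bound (34.9%), against 11 of 2102 members of the 5 somatic lists (0.523%), a difference of 34.3 percentage points (two-sided Fisher's exact p = 1.17e-76), which was 16.4 points with the narrower promoter window (exact p = 1.1e-35).

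Proliferation genes and most kinds of housekeeping genes were also bound more often than other genes. No list from untagged worms was used, so high occupancy in any ChIP was not told apart from XND-1 binding. The same limit holds for promoters and the other gene lists. DNA replication had 18 of 34 members bound (52.9%, exact 95% interval 35.1% to 70.2%, adjusted exact p = 1.98e-12), with pcn-1 (1217), which encodes the sliding clamp, rnr-1 (1002), mcm-2 (966) and psf-3 (378). The kinetochore, centrosome and cell cycle list had 23 of 53 bound (43.4%, 29.8% to 57.7%, adjusted exact p = 3.45e-13), with cyb-2.2 (642), csc-1 (633), knl-3 (511) and tac-1 (433). Cytosolic ribosomal proteins had 34 of 81 bound (42%, 31.1% to 53.5%, adjusted exact p = 1.73e-18), led by rpl-20 (585), rpl-3 (528), rpl-35 (525) and rpl-29 (293). The proteasome had 9 of 33 bound (27.3%, 13.3% to 45.5%, adjusted exact p = 0.000328), led by rpn-2 (451), pas-6 (374), rpn-6.1 (268) and rpn-3 (213). Translation factors and tRNA synthetases had 13 of 68 bound (19.1%, 10.6% to 30.5%, adjusted exact p = 0.000658), led by hars-1 (656), eif-3.C (274), eef-2 (268) and eif-2A (241). Spliceosome and SR protein genes had 8 of 42 bound (19%, 8.6% to 34.1%, adjusted exact p = 0.00745; an excess of 12.4 percentage points, 19.6 without replicate 2), with rnp-8 (703), rsp-6 (284), snr-4 (164) and rsp-5 (144). Its strongest member, rnp-8, is an RNA-binding protein of the germline that is also in the translational control list. Mitochondrial respiratory chain and ribosome genes had 21 of 125 bound (16.8%, 10.7% to 24.5%, adjusted exact p = 0.000122), with mrpl-37 (511), cox-16 (492), cox-5B (486) and ndub-8 (395). Histone genes had 7 of 72 bound (9.72%, 4% to 19%) and did not pass the test (adjusted exact p = 0.374). Their excess over other genes, 3.05 percentage points, was 0.578 without replicate 1 and 7.24 without replicate 2, where it was called (adjusted exact p = 0.0325), and −0.926 among the 921 strongest peaks. The highest scores were 217 at the shared promoter of his-67 and his-68, 121 at his-74 and 81.7 at his-59. With the promoter window narrowed to 200 bp upstream and 100 bp downstream, the calls of ribosomal proteins (adjusted exact p = 0.26), proteasome (0.371), spliceosome (0.228) and translation factors (0.113) were lost. Summits of the 34 bound ribosomal protein genes lay at a median of 289 bp upstream, and only 5 (14.7%) were inside that window. The share inside was 31.5% for all bound housekeeping genes, 44% for germline and 63.4% for proliferation genes. For ribosomal proteins the lost call thus reflects where the summits lay. The mitochondrial call was lost among the 921 strongest peaks (adjusted exact p = 0.18). Over all alternatives the excess over other genes ran from 2.89 to 48.9 percentage points for ribosomal proteins (35.4 in the main setting), from 2.77 to 37.9 for the proteasome (20.6), from 3.86 to 32.3 for the spliceosome (12.4), from 4.07 to 20.4 for translation factors (12.5), from 2.72 to 16.7 for mitochondrial genes (10.2) and from 23 to 48.2 for the kinetochore list (36.8).

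**Figure D3:**
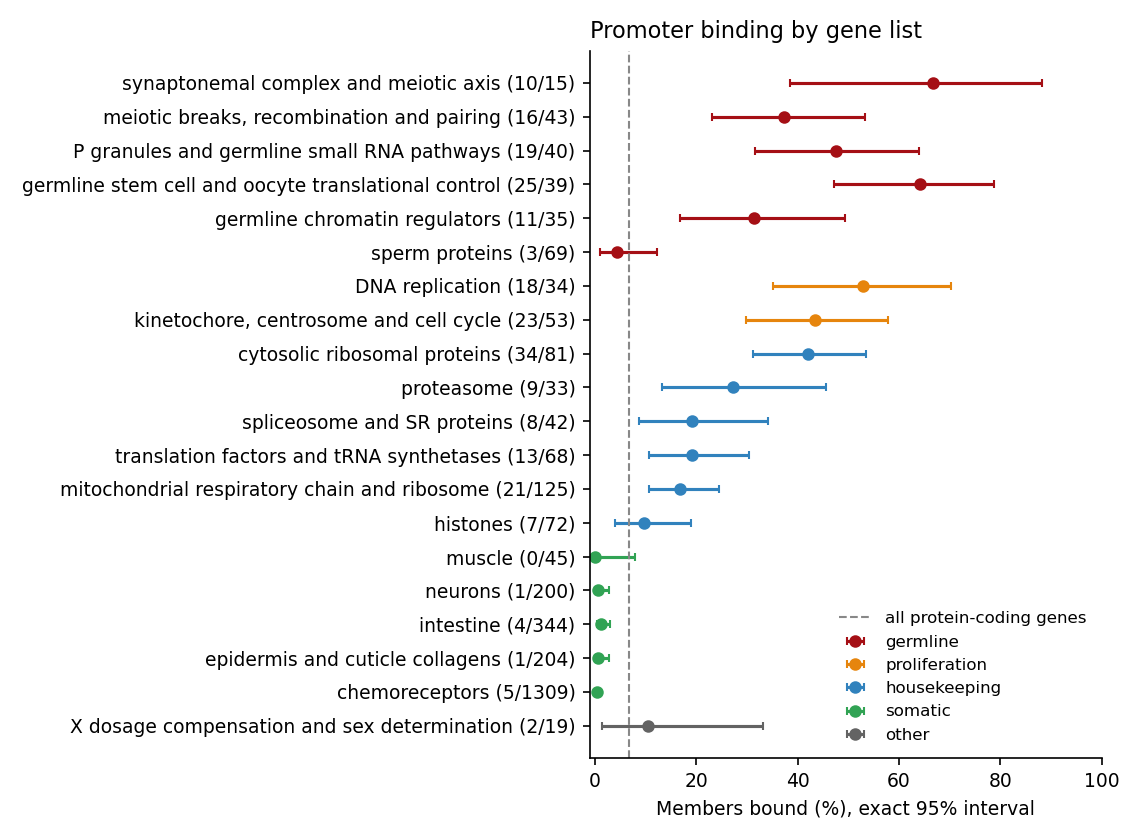
Percent of the members of each gene list with a summit in the promoter window (x axis), with exact 95% intervals, bound and total members in brackets (y axis), colours for the kind of list, and a dashed line at 6.68% for all protein-coding genes. Synaptonemal complex genes stand at 66.7% and chemoreceptors at 0.382%.

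Somatic genes were rarely bound. Chemoreceptor genes had 5 of 1309 members bound (0.382%, adjusted exact p = 7.54e-32), neuronal genes 1 of 200 (0.5%, adjusted exact p = 4.28e-05), the intestinal list 4 of 344 (1.16%, adjusted exact p = 3.81e-06), and epidermal and cuticle collagen genes 1 of 204 (0.49%, adjusted exact p = 4.28e-05). No muscle gene of 45 was bound (exact 95% upper limit 7.87%), which did not pass the test (adjusted exact p = 0.0858), but the muscle list was called lower with a window of 1000 bp upstream and 500 bp downstream (−8.52 percentage points against other genes, adjusted exact p = 0.0359) and against genes with a three-letter style name only (−8.37 points, adjusted exact p = 0.0359). With the window of 200 bp upstream and 100 bp downstream the other 4 somatic lists kept their calls at −2.46 to −3.44 points, against −5.61 to −6.74 in the main setting. That window left 658 bound genes in all, against 1334, which by itself makes these differences smaller. The bound exceptions were sri-5 (169), srh-16 (158), srw-90 (117), srz-97 (81.8) and str-206 (77.1, outside the naming rule and named after its value was seen), the neuronal gene unc-31 (90.6, at an annotated 5′ end inside the gene), the collagen gene col-38 (113), and the C-type lectin genes clec-87 (546), clec-88 (538), clec-91 (332) and clec-126 (87.4), which entered the intestinal list by their name prefix. That prefix makes up 240 of the 344 members and holds genes expressed outside the intestine, so the value describes mostly C-type lectin genes; none of the other members was bound (exact 95% upper limit 3.48%). X dosage compensation and sex determination genes had 2 of 19 bound (10.5%, adjusted exact p = 0.385; 3.85 percentage points against other genes, −1.11 to 10.5 over the alternatives, the lowest without replicate 1), tra-1 (246) and dpy-26 (83).

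Within housekeeping lists, X members were less often bound than autosomal members. None of 14 X members and 92 of 407 autosomal members (22.6%) were bound, a difference that reached the threshold narrowly (two-sided Fisher's exact p = 0.0469) and missed it without replicate 1 (−20.9 percentage points, exact p = 0.0831). Among the 921 strongest peaks the difference was −11.8 points (exact p = 0.385), with the narrower promoter window −7.62 (exact p = 0.612), against −22.6 in the main setting, and in the looser list −35.9 (exact p = 0.00313).

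Among single genes fixed beforehand, spo-11, which makes the meiotic breaks, was bound with a score of 360 and its summit 10 bp upstream of its 5′ end at IV:11124872. Synaptonemal complex genes syp-2, syp-4 and syp-3 had scores of 492, 167 and 75.2, the syp-2 summit at V:5536619 being the one counted for cox-16. No IDR-thresholded summit lay in the promoter windows of xnd-1, unc-119 (a common transgene marker), him-17, him-5, him-8 or syp-1. With the window of 1000 bp upstream and 500 bp downstream him-5 was bound, and in the looser list him-17. In the pooled list him-17 had a peak with a score of 46.7 at rank 2802 and unc-119 one of 27.5 at rank 6150. No pooled peak had its summit in the windows of xnd-1, him-5, him-8 or syp-1. The nearest IDR-thresholded summit to a 5′ end of him-5 was 432 bp away, on the downstream side, past the 200 bp limit of the window.

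The DNA at the summits held recurring sequence words. Of 2080 pairs of 6-base words with their reverse complements, 320 were more frequent within 50 bp of summits than in flanks 300 bp away and 312 were less frequent (exact McNemar tests, Benjamini-Hochberg adjusted). GGCGCA occurred in 20.7% of summit windows and 2.8% of flank windows (adjusted exact p = 1.88e-70), AGGCGC in 20.2% and 2.39% (4.29e-67), GAGACC in 21% and 3.75% (5.68e-59), and ACCGTA in 19% and 2.96% (1.37e-52). GCGCGC occurred in 12% and 0.978% (1.54e-42). In the looser list the excess of the first 4 over flanks was 9.89 to 11.9 percentage points, against 16.1 to 17.9 in the main setting, and with windows of 25 bp to either side it was 9.42 to 11.2 for GGCGCA, AGGCGC and ACCGTA. Among the 921 strongest peaks it was 24.3 for ACCGTA. At least 1 of the 10 words with the smallest p stood in 57.9% of summit windows and 16.6% of flank windows. Summit windows had a GC content of 41.8% and flanks 36.1%, and the test does not remove differences in base composition.

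**Figure D4:**
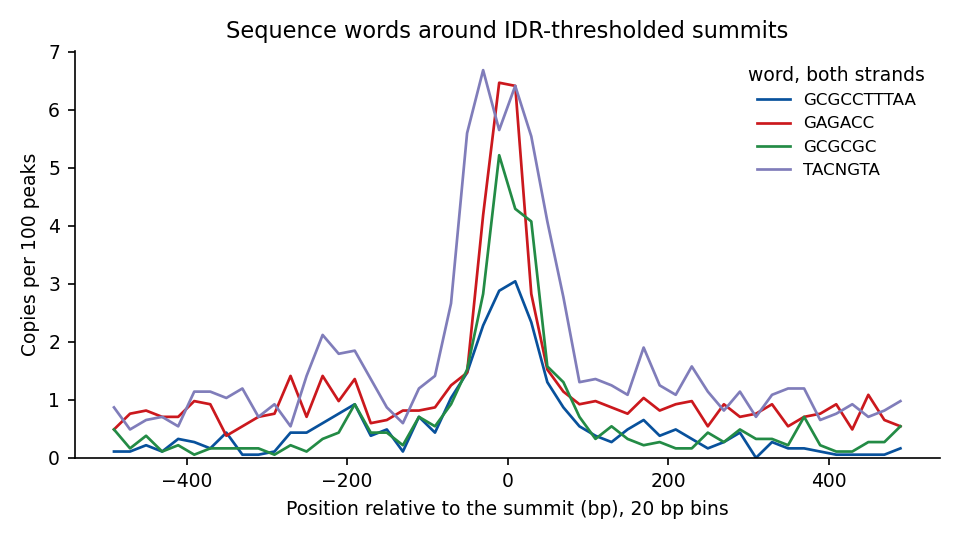
Copies of 4 sequence words per 100 peaks (y axis) in 20 bp bins relative to the summit (x axis), both strands counted; N stands for any base. All 4 peaked within 50 bp of the summit; GCGCCTTTAA and TACNGTA were chosen after the data were examined.

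Non-coding RNA genes also lay near peaks more often than shifts give. Within 200 bp of small nuclear RNA (snRNA) genes stood 48 summits, where 100000 circular-shift permutations gave 1.31 on average and at most 15, and within 200 bp of small nucleolar RNA (snoRNA) genes stood 63, where shifts gave 3.86 and at most 20 (both adjusted permutation p = 1.75e-05, one-sided). The numbers were 22 against 3.49 for tRNA genes and 146 against 60.9 for other non-coding RNA genes (both adjusted permutation p = 1.75e-05), and 6 against 1.97 for microRNA genes (adjusted permutation p = 0.0265). For piRNA genes 20 summits were near and shifts gave 58.9 (adjusted permutation p = 1 in the direction tested), and no summit lay near rRNA genes (adjusted permutation p = 1). Among the 921 strongest peaks the calls of tRNA and microRNA genes were lost (both adjusted permutation p = 0.143). The share of summits near tRNA genes fell there from 1.2% to 0.434%, whereas that near microRNA genes stayed at 0.326%. MicroRNA genes also lost their call when the summit had to lie inside the gene (adjusted permutation p = 0.461). Inside the gene itself lay 0.761% of summits for snRNA against 2.61% within 200 bp, 0.652% against 3.42% for snoRNA, 0.163% against 1.2% for tRNA (adjusted permutation p = 0.0372) and 3.31% against 7.93% for other non-coding RNA genes, with calls kept. In the looser list 2.31% of summits lay within 200 bp of tRNA genes. The shifts do not keep summits in protein-coding promoters, where most of them lay. Closeness to such promoters was set apart only for snRNA and snoRNA genes, so it stays open for tRNA, microRNA and other non-coding RNA genes. Non-coding RNA genes of several kinds are frequent high-occupancy sites in ChIP-seq of worms, and no list from untagged worms was used here.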

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

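The deposited q values put 1141 further peaks of the pooled ce11 list at the same highest value as every IDR-thresholded peak, although these 1141 fell below the IDR threshold. They were not in the IDR-thresholded list on which the report's tests rest, but they are part of its rank bins and of the looser list, and the him-17 peak at rank 2802 is one of them. Their scores ran from 44.4 to 65.6. Of them 28 lay on X (2.45%), against 0.543% of the IDR-thresholded peaks, and 44.8% had their summit in a promoter window, against 60.9%. Whether they mark binding was not tested.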

How the results depend on the processing

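Over 8 alternatives the share of peaks on X stayed between 0.217% and 1.47%, with a largest p of 6.49e-69, and promoters, chromosome centres and the difference between germline and somatic lists kept direction and threshold under every alternative run, although the narrower promoter window, 200 bp upstream and 100 bp downstream, brought the promoter share from 60.9% to 32.3% and the difference between germline and somatic lists from 34.3 points to 16.4, and the middle 50% of autosomes, a longer stretch, held 59.3% of summits. Lists without peaks near snRNA, snoRNA or tRNA genes, nearest genes for the germline against somatic comparison, and X without 200 kb at chromosome ends were chosen after seeing the data. The number of lists called stayed between 12 and 17 (16 in the report), and 210 of 220 alternatives for single lists gave the same call, but values moved by over 1.5 times in 16 of 20 lists with the narrower window, in 14 among the 921 strongest peaks and in 9 with the looser list. The narrower window left 658 bound genes and the 921 strongest peaks 739, against 1334, which by itself makes differences in points smaller. X against autosomes within housekeeping lists, a difference of −22.6 points, was −11.8 among the 921 strongest peaks and −7.62 with the narrower window, neither past the threshold; both leave fewer bound genes. It ran from −23.6 to −20.9 with 1 replicate left out, past the threshold only without replicate 2, and was −35.9 in the looser list. Non-coding classes called fell from 5 to 3 among the 921 strongest peaks, a smaller set. The share of IDR-thresholded peaks overlapped was 86.6% and 88% for replicates 1 and 2 with summits within 100 bp and 79% and 78.7% with 50% reciprocal overlap, both of them stricter matches. With the whole list of each replicate in place of its top 1841 peaks it was 99.9% and 100% and rho 0.875. On ce10 replicate 2 gave 89.7%; the cause was not tested. Not called in the report either way, the dosage compensation list ran from −1.11 points to 3.86 with 1 replicate left out, and histones fell from 3.05 points to −0.926 among the 921 strongest peaks. Summits near rRNA genes, 0% in the main setting, rose to 0.0543% without replicate 1 and to 0.0272% in the looser list. The cause of these changes was not tested. Of 96 named genes 90 were bound, and of these 3 lost their peak without replicate 1 (spe-5, clec-126 and dpy-26), 11 among the 921 strongest peaks and 51 with the narrower window; of the others, him-5 gained a peak with the window of 1000 bp upstream and 500 bp downstream and him-17 in the looser list. The peak lists hold no read counts, so depth limits cannot be given.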

Other observations

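Gene families by name prefix, and every test in this part except those on promoters beside snRNA and snoRNA genes, on their overlap by both replicates, on weaker peaks and on the density of the 10-base word, were chosen after the results were seen. Of 240 families with at least 8 protein-coding members, 13 were bound more and 7 less often than other genes (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted). Beyond families in the fixed lists, nuclear pore genes (npp) had 10 of 26 members bound (adjusted exact p = 0.000135), led by npp-3 (774) and npp-9 (426). Genes with the name prefix cpg had 5 of 13 bound (adjusted exact p = 0.0167), with cpg-2 (1024) and cpg-4 (840) next to cpg-1. High mobility group genes (hmg) had 4 of 9 bound (adjusted exact p = 0.0247) and cyclophilin genes (cyn) 5 of 16 (adjusted exact p = 0.0371). Nuclear hormone receptor genes (nhr) had 1 of 269 bound (adjusted exact p = 1.88e-05), and F-box A genes (fbxa) 2 of 170 (adjusted exact p = 0.0229).

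The word most frequent at autosomal summits among 10-base words was GCGCCTTTAA, within 50 bp of 211 summits. The genome held 2698 copies on autosomes, 32.7 per Mb, and 33 on X, 1.86 per Mb. Near a summit, within 100 bp, lay 11% of the autosomal copies and 1 of the 33 X copies (3.03%, exact 95% interval 0.0767% to 15.8%; Fisher's exact p = 0.253). The word often stood at 1 of a few distances from GAGACC, though 34 arrangements were seen. Of 280 peaks with the word within 100 bp of the summit, 162 also held GAGACC, on either strand, within 60 bp of it, and the 3 commonest of 242 possible arrangements accounted for 87 occurrences, GAGACC starting 26 bp before the word in 41 peaks and 23 bp before it in 27, and its reverse complement 41 bp before it in 19. TACNGTA, another word at summits, stood in 53% of the 185 strongest peaks and 13% of the 184 weakest, and in 62.1% of peaks with GCGCCTTTAA against 20.7% of those without.

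The scarcity of peaks on X was set against 3 explanations. X members of the gene lists numbered 186, and at each list's autosomal share 7.52 of them would have been bound, whereas none was (exact one-sided Poisson-binomial p = 0.000107), which argues against gene content, as far as these lists describe it, as the whole cause. The result rests on few genes. Most of the 186 were in somatic lists, which added at most 0.424 expected genes each. The largest parts came from 4 P granule and small RNA genes (2.11) and 3 germline chromatin regulators (1.03). X made up 10.5% of the 8155 weakest peaks of the pooled list (exact 95% interval 9.89% to 11.2%), above its interval in the IDR-thresholded list. This argues against an X chromosome that could not be read at all. The share was still under the 17.7% of chromosome length that is X. An X that was read less well than autosomes was thus not excluded. The 10 words with the smallest p at summits stood on X at 0.674 (exact 95% interval 0.648 to 0.701) to 1.11 (1.07 to 1.16) of their autosomal density, but this decides nothing, because at most 3.03% of a word's autosomal copies lay within 50 bp of summits and the other copies alone would hold the ratio up. For peaks without GCGCCTTTAA within 50 bp the density ratio of X to autosomes was 0.0288 (0.0138 to 0.053). These were 1630 of the 1841 peaks and all 10 on X, so the ratio could hardly differ from that of all peaks. Scarcity of the exact word within 50 bp does not account for peaks that lack it there. Altered copies were not searched, and 280 peaks held the word within 100 bp, so scarcity of a broader element stays open. For peaks with the word, 211 on autosomes and 0 on X, the explanation stays open. The word's own ratio, 0.057, lies above the interval of the ratio of all 1841 peaks, 0.0254 (0.0122 to 0.0469), as a word present without peaks would give, but not by more than its spread (0.0391 to 0.0802). No biological explanation was tested, since the design has 1 group.

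Peaks near snRNA and snoRNA genes numbered 110. Outside protein-coding promoter windows lay 78 of them, where shifts gave 4.19 on average and at most 24, which argues against neighbouring or host gene promoters as the whole cause. Top peaks of both replicates overlapped 86.4% of the 110 (exact 95% interval 78.5% to 92.2%), which decides nothing, because the IDR-thresholded list was made from both. Of the top 1841 peaks of replicate 1, taken from its own list, top peaks of replicate 2 overlapped 89.1% of those near these genes (81.3% to 94.4%); in the other direction it was 88.5% (80.7% to 93.9%), which argues against calls made in 1 replicate. High occupancy in any ChIP of worm chromatin stays open, since no list from untagged worms was used, and no biological explanation was tested.

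Sequence words were less frequent at weaker peaks. At least 1 of the 10 words with the smallest p stood in 74.6% of the 185 strongest peaks and 38.6% of the 184 weakest. Counted over 200 bp to either side, the mean excess of these words over flanks at the 920 weaker peaks was 0.457 of that at the 921 stronger peaks (bootstrap 95% interval 0.396 to 0.524), which argues against less exact summits as the whole cause. The 920 weaker peaks still bound 9.96% of germline list members and 3.09% of other genes (Fisher's exact p = 7.92e-07). For the 921 stronger peaks the shares were 26.1% and 3.43%. This argues against weaker peaks that are all background placed without regard to gene group. Background that itself favours germline genes stays open, since no list from untagged worms was used. A mixture of bound sites and background may remain and was not tested.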
